A study of Homo sapiens with 6 samples.

How the data were processed

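RNA sequencing was made from AGS cells, an established line of human gastric adenocarcinoma epithelial cells, after transient transfection with a negative control (NC) or with mimics of the microRNA miR-3648. Each of the 2 groups held 3 libraries, and group and replicate number were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Total RNA was extracted with TRIzol and column purification, and libraries were made with a strand-specific kit, per the labels' protocols.

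The values are FPKM, a fragment count scaled by transcript length and by the mapped fragments of the library, as the authors deposited them in 1 table of the whole series. StringTie 1.3.3 and cutadapt, with no version for cutadapt, and the genome build GRCh37 are named in the submitters' processing notes. The aligner, the annotation release and the strand setting of the quantification are not given in the sources used here. StringTie assigns reads to gene models by an assembly of transcripts, so genes that overlap on the same strand can exchange reads, and copies such as processed pseudogenes can share them. The deposited table used here lists 11187 protein-coding genes, each reaching at least 0.527 FPKM in 1 or more libraries, and the rule by which genes were listed is not stated. FPKM sums over the listed genes ran from 208274 to 222947 per library, which is part of each library and not its depth. Low values did not fall on steps of whole reads: among 312 genes with a value below 0.5 in the lower of NC replicates 1 and 2, no more than 3 genes shared a ratio between these libraries to 4 digits. The depth is therefore unknown, and no counting interval is given. FPKM is relative to the library total, so an equal change of all genes cannot be seen.

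Values were transformed as log2(FPKM + 1), without further scaling. A gene was tested where its mean over the 6 libraries was at least 1 FPKM, which left 10286 genes and removed 901. Groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, two-sided, and with Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. Fold changes are mimic minus NC on the log2(FPKM + 1) scale, which understates the change of genes of low expression. Since the values are FPKM, the count models planned for raw counts were not run. FRAT1 lay below the filter and was compared with an exact permutation test over the 20 assignments of 6 libraries to 2 groups of 3, which cannot give a two-sided p below 0.1. The limma fit was tested on simulated libraries with the gene variances that limma fitted to these data, 10286 genes and 200 changed genes. It called 90 of 100 genes changed by 1 log2 unit, 45 of 100 changed by 0.5 and 12 of 10086 unchanged genes. Noise was drawn independently for each gene and library, so no trend shared by many genes, such as one with GC content, was simulated. These rates need not hold for the real libraries.

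The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took FRAT1, FRAT2 and MYC, and the 10 largest rises and 10 largest falls among called genes whose groups did not overlap. It also took up to 4 members of each list with the smallest p, and the 5 called genes of largest absolute change with a mean of at least 50 FPKM. Some of the genes it took are not reported here. The 24 lists covered the Wnt pathway core, Wnt targets, MYC-induced genes, epithelial junctions, mesenchymal genes, adhesion and invasion, cell cycle, p53 targets, interferon-stimulated genes, NF-kB genes, immediate-early genes, the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, cytosolic ribosomal proteins, nuclear and mitochondrial respiratory chain genes, histones, microRNA machinery, gastric lineage genes, apoptosis regulators, and markers of fibroblasts, leukocytes and endothelium. Lists were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation, with fry, which does not compare a list with other genes, and with the rank form of camera. Adjustment was over the 24 lists.

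Seed sites were counted in the longest 3' UTR of each gene in GENCODE v29, matched by Ensembl gene identifier. That annotation is on GRCh38, so it gave sequence properties and no coordinates, and coordinates in the text are those of the deposited table on GRCh37. The mature sequence AGCCGCGGGGAUCGCCGAGGG was taken as miR-3648, from general knowledge and not checked against a database here. Its 7mer-m8 site is CCGCGGC and its 7mer-A1 site is CGCGGCA. The median change of genes with the site was ranked among the 56 words of 7 letters made of C and G with 2 CpG dinucleotides each. Transcript GC content and length were available for 10186 of the tested genes (99.0%).

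Alternatives were other pseudocounts (0.1 and 0.5), no filter or a filter of 5 FPKM, upper-quartile and quantile scaling, no intensity trend, library weights, a replicate block, a minimum absolute change of 1 log2 unit, and leaving out each library in turn. After the data were seen, a loess correction (span 0.3) of each library for transcript GC content was added, alone, with transcript length, and without NC replicate 3. The rank form of camera was also added then, as was camera with an estimated correlation after GC correction.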

Results

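The transcriptomes of AGS gastric adenocarcinoma cells were compared 3 libraries against 3, after transfection with NC or with miR-3648 mimics. FPKM were available for 11187 protein-coding genes, of which 10286 passed the filter. The depth of each library is unknown. The median FPKM over listed genes lay between 6.33 and 6.65 in the 6 libraries, and the 10 most abundant genes held 17.0% to 18.2% of the FPKM sum. The title of the series names FRAT1, FRAT2 and MYC as parts of a loop with miR-3648 in metastasis and invasion, so these genes were examined first. The level of miR-3648 itself was not analysed here.

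FRAT2, which encodes a GSK3-binding protein of the Wnt pathway, was measured at 7.24 ± 0.505 FPKM in NC and 5.68 ± 0.170 FPKM in mimic libraries (SD, n = 3 each). All 3 mimic values lay below all 3 NC values, with a log2 fold change of -0.30 (SE 0.08), and the difference did not pass the limma test after adjustment (adjusted p = 0.21). Its paralog FRAT1 was near the lower end of the table, at 0.808 ± 0.164 FPKM in NC and 0.366 ± 0.117 FPKM in mimic libraries (SD, n = 3 each). The FRAT1 groups did not overlap either, and the exact permutation test gave p = 0.1, the smallest value that 3 against 3 can reach. In a limma fit without the filter, FRAT1 had a log2 fold change of -0.40 over the 6 libraries (adjusted p = 0.19). Without NC replicate 3, which stood apart from NC replicates 1 and 2, FRAT2 had a limma adjusted p of 0.030. FRAT1 had one of 0.041 there, again without the filter, and 1527 of the tested genes passed in that setting. With a correction for transcript GC content as well, chosen after the data were seen, the adjusted p was 0.18 for FRAT2 and 0.17 for FRAT1. Both transcripts are rich in GC, at 60.2% for FRAT2 and 62.25% for FRAT1, against a mean of 49.4% over tested genes. Across tested genes the fold change ran against GC content (Spearman's rho -0.50). With GC correction over all 6 libraries the log2 fold change was -0.19 for FRAT2 and -0.28 for FRAT1 (limma adjusted p = 0.16 and 0.15). The adjusted p ranged over all alternatives from 0.027 to 0.57 for FRAT2 and from 0.0064 to 0.50 for FRAT1.

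MYC, which encodes the transcription factor c-Myc, was at 1.71 ± 0.404 FPKM in NC and 7.86 ± 10.2 FPKM in mimic libraries (SD, n = 3 each). The mimic mean rested on replicate 1, at 19.6 FPKM, while mimic replicates 2 and 3 were at 2.09 and 1.85 FPKM and the NC libraries between 1.25 and 2.0 FPKM. MYC did not pass the test (log2 fold change 1.08, SE 0.72, adjusted p = 0.50), and without mimic replicate 1 the log2 fold change was 0.14. On GRCh37, FRAT1 (ENSG00000165879) lies on chromosome 10 from 99079024 to 99081672 on the plus strand, FRAT2 (ENSG00000181274) on the same chromosome from 99092254 to 99094466 on the minus strand, and MYC (ENSG00000136997) on chromosome 8 from 128747680 to 128753680. No other listed gene overlapped any of the 3.

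**Figure D1:**
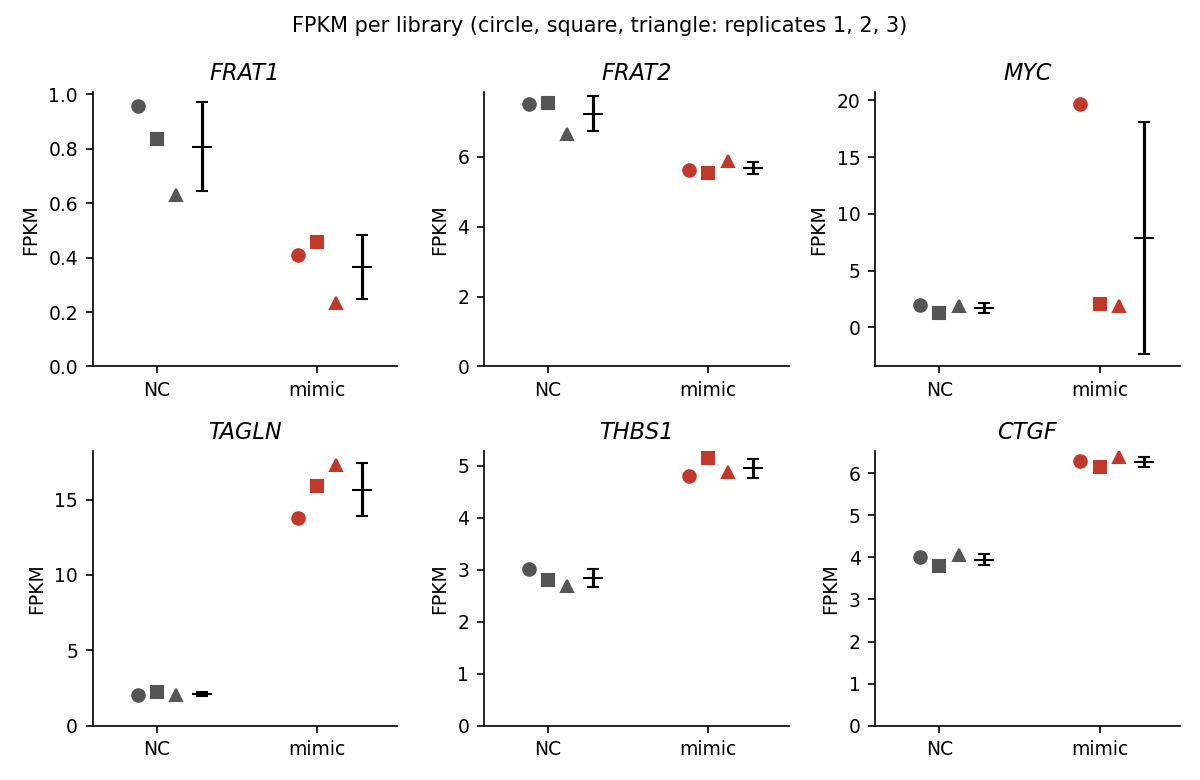
FPKM of FRAT1, FRAT2, MYC, TAGLN, THBS1 and CTGF in each NC (grey) and mimic (red) library, with the group mean and SD in black (n = 3). MYC stands at 19.6 FPKM in mimic replicate 1 and at or below 2.09 FPKM in the other libraries, while the groups of the remaining genes do not overlap.

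TAGLN, which encodes the actin-binding protein transgelin, rose with the mimics from 2.09 ± 0.126 to 15.7 ± 1.77 FPKM (SD, n = 3 each; log2 fold change 2.43, SE 0.10, limma adjusted p = 0.00028). MYL9, a myosin regulatory light chain, rose from 25.3 ± 2.79 to 64.0 ± 0.942 FPKM (log2 fold change 1.31, SE 0.09), and the tropomyosin gene TPM4 from 49.3 ± 2.08 to 91.6 ± 15.7 FPKM (log2 fold change 0.87, SE 0.12). Gamma-actin, ACTG1, rose from 146 ± 17.4 to 231 ± 4.71 FPKM, although its reads can be shared with the near-identical beta-actin gene and with processed pseudogenes. PTPN14, a phosphatase that binds the coactivator YAP, rose from 4.49 ± 0.273 to 11.1 ± 0.178 FPKM (log2 fold change 1.15, SE 0.08).

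Other large rises were in the tight-junction gene CLDN2, from 2.42 ± 0.236 to 5.94 ± 0.498 FPKM, and the kinase HIPK1, from 7.0 ± 0.447 to 14.5 ± 0.421 FPKM (SD, n = 3). DPYSL3 and G3BP2, a stress granule protein gene, rose by 0.87 and 0.85 log2 units. GANAB, the glucosidase II subunit of the endoplasmic reticulum, rose from 57.5 ± 3.29 to 92.3 ± 5.5 FPKM. The largest fold change among called genes belonged to the read-through gene PTGES3L-AARSD1 (chromosome 17, 41102543 to 41132545), from 0.106 ± 0.0293 to 5.82 ± 0.323 FPKM. AARSD1, which lies inside it on the same strand (41102543 to 41116515), fell from 6.41 ± 0.963 to 1.93 ± 0.0420 FPKM. Their summed FPKM was 6.52 ± 0.992 in NC and 7.75 ± 0.362 in mimic libraries, with an exact permutation p of 0.2 (n = 3 each), so neither value can be read as a change of the locus.

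FTH1, the ferritin heavy chain, fell with the mimics from 595 ± 112 to 268 ± 42.1 FPKM (SD, n = 3 each; log2 fold change -1.14, SE 0.15, limma adjusted p = 0.043), a gene with many processed pseudogenes that can share its reads. MAP1LC3B, which encodes the autophagosome protein LC3B, fell from 20.1 ± 1.3 to 8.99 ± 0.338 FPKM (log2 fold change -1.08, SE 0.08), and DRAM1, a lysosomal membrane protein gene, from 25 ± 0.937 to 17.4 ± 0.643 FPKM. The palmitoyltransferase ZDHHC20 fell from 27.0 ± 2.35 to 10.2 ± 1.58 FPKM (log2 fold change -1.32, SE 0.12). GRHL3, a grainyhead transcription factor of epithelia, fell from 14.2 ± 1.24 to 6.88 ± 1.12 FPKM, and the histone variant gene H2AFX from 39.9 ± 5.67 to 20 ± 1.29 FPKM. MANSC1 fell by 0.99 log2 units, ZNF385A by 0.85, the salivary cystatin gene CST4 by 0.74 and the growth factor gene TGFB3 by 0.71. RRBP1, a ribosome-binding protein of the endoplasmic reticulum, fell from 122 ± 11.6 to 74.4 ± 4.25 FPKM.

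In all, 42 of 10286 genes passed the limma test, 24 higher and 18 lower in mimic libraries, and the groups of all 42 were non-overlapping. Of the tested genes, 22.2% had non-overlapping groups, and 1506 had an unadjusted p under 0.05. Genes that vary independently and do not differ between groups would give a share near 10%. A trend shared by many genes, such as one with GC content, can lift that share, so the excess does not measure an effect of the mimics. The 16 called genes that the naming rule did not take were HEPHL1, SERPINB2, HSD3B1, F3, TM4SF1, STX12, CHI3L1, CD22, RPL26L1 and MLLT11, which rose by 0.54 to 0.78 log2 units, and SERINC5, DDA1, RRP1B, KPNA6, C9orf152 and DRAM1, whose log2 fold changes lay between -0.68 and -0.50. MAP1LC3B, CLDN2, TAGLN, GRHL3, TGFB3, DDA1 and MLLT11 overlap a listed gene on the other strand, and the strand setting of the quantification is unknown. The count depended on single libraries: 1527 genes were called without NC replicate 3, and 8, 10, 11, 8 and 9 without NC replicate 1, NC replicate 2 and mimic replicates 1, 2 and 3. Without NC replicate 3 all 42 genes were still called, against 7, 9, 8, 5 and 7 of them in the other 5 cases.

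**Figure D2:**
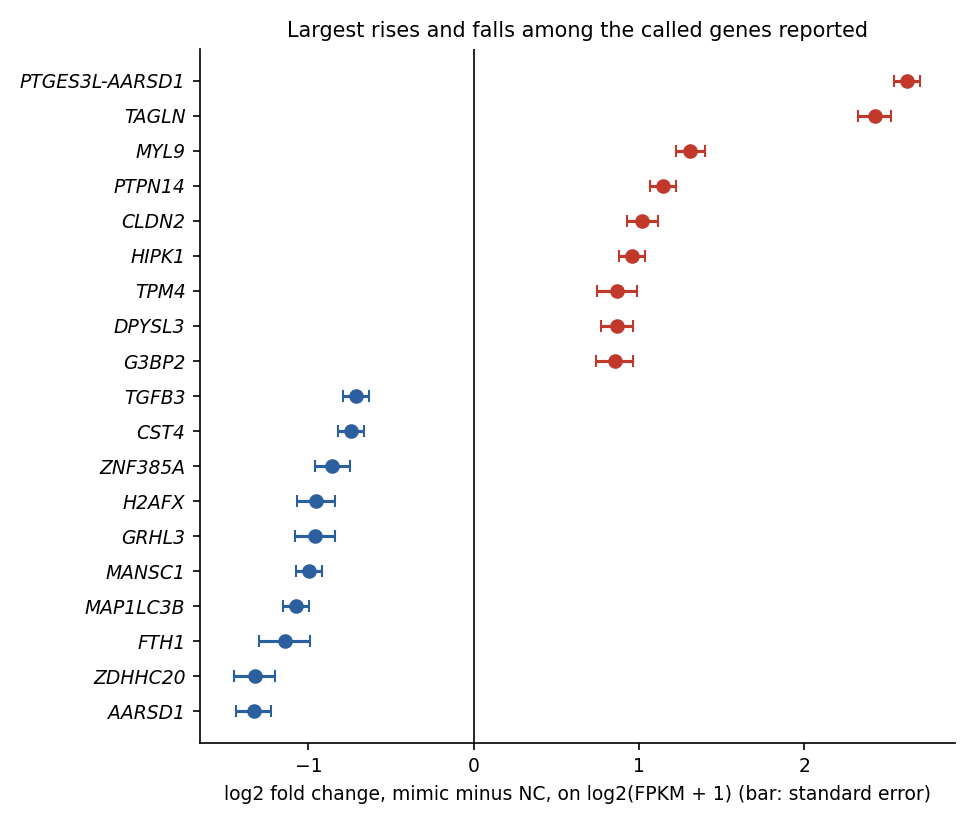
Log2 fold change (points) and standard error (bars) of the largest rises and falls among called genes that are reported here, on the log2(FPKM + 1) scale. PTGES3L-AARSD1 (2.62) and TAGLN (2.43) lie farthest to the right, and AARSD1 (-1.33) and ZDHHC20 (-1.32) farthest to the left.

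Wnt pathway genes were examined as 2 lists, since FRAT1 and FRAT2 act in that pathway. The 28 tested core pathway genes lay lower in mimic libraries as a group, with 22 negative and 6 positive log2 fold changes and a median of -0.13 (camera adjusted p = 0.0061). The adjusted p was 0.84 with an estimated correlation. No core gene passed singly over all genes or adjusted over the list alone. The scaffold gene AXIN1 was at 5.65 ± 0.744 FPKM in NC and 3.90 ± 0.173 FPKM in mimic libraries, the receptor gene FZD7 at 17.7 ± 1.95 and 13.3 ± 0.427 FPKM, and PORCN, needed for Wnt secretion, at 2.14 ± 0.450 and 1.48 ± 0.0958 FPKM (SD, n = 3). In NC replicate 3 the core list lay at a median of -0.16 log2 units from NC replicates 1 and 2, where all tested genes lay at -0.03.

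The 24 tested Wnt target genes did not move as a group (median -0.04, mean 0.02, camera adjusted p = 0.67). None passed over all genes, while 3 were higher and 3 lower when adjusted over the list alone. CYR61, a matricellular gene, was at 9.83 ± 1.05 FPKM in NC and 15.9 ± 1.20 FPKM in mimic libraries (log2 fold change 0.64, adjusted p = 0.073). Lower values in mimic libraries were measured for the cyclin gene CCND1 (141 ± 4.96 and 113 ± 4.57 FPKM), the transcription factor gene SP5 (39.4 ± 5.89 and 26.5 ± 2.19 FPKM) and KREMEN1 (4.74 ± 0.671 and 3.10 ± 0.207 FPKM; SD, n = 3). The MYC-induced list of 44 tested genes had a median of 0.06 and did not pass (camera adjusted p = 0.22), with NPM1 at 204 ± 25.1 FPKM in NC and 242 ± 5.16 FPKM in mimic libraries, NOP58 at 38.2 ± 5.38 and 46.0 ± 1.86 FPKM, and PUS1 at 4.54 ± 0.286 and 3.13 ± 1.01 FPKM. After GC correction, chosen after the data were seen, that list passed at the preset correlation (adjusted p = 0.0048, higher in mimic libraries) but not with an estimated correlation (adjusted p = 0.42).

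Mesenchymal and EMT genes were higher in mimic libraries as a group (16 tested, 12 positive, median 0.21, camera adjusted p = 0.00024). The adjusted p was 0.57 with an estimated correlation and 0.089 without NC replicate 3. Of the 16, 3 rose over all genes, TAGLN, THBS1 and CTGF, and 6 when adjusted over the list alone, and none fell. The matricellular genes THBS1 and CTGF rose from 2.83 ± 0.171 to 4.95 ± 0.182 FPKM and from 3.95 ± 0.135 to 6.27 ± 0.119 FPKM (SD, n = 3). TAGLN, THBS1 and CTGF encode an actin-binding protein and secreted matrix-associated proteins and are not themselves transcription factors of EMT. The list was fixed with 39 symbols, some of them second names, and VIM, CDH2, FN1, ZEB1 and ZEB2 were not among the tested genes. SNAI1, a transcription factor of EMT that was tested, had a log2 fold change of 0.07 (limma adjusted p = 0.73). The group result is therefore not a measure of EMT. In NC replicate 3 the list lay at a median of -0.12 log2 units from NC replicates 1 and 2.

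The invasion list did not move as a group (30 tested, median -0.0046, camera adjusted p = 0.57). None of its genes passed over all genes. The integrin gene ITGB1 was at 73.0 ± 7.88 FPKM in NC and 98.3 ± 9.86 FPKM in mimic libraries (SD, n = 3). Epithelial junction genes did not pass either (32 tested, median -0.09, adjusted p = 0.60), with DSC2 at 11.2 ± 0.953 and 14.6 ± 0.352 FPKM, DSP at 114 ± 6.68 and 97.7 ± 1.62 FPKM and EPCAM at 182 ± 4.03 and 202 ± 4.90 FPKM.

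Cell cycle genes lay lower in mimic libraries as a group (46 tested, 14 positive, median -0.12, camera adjusted p = 0.0061). The adjusted p was 0.57 with an estimated correlation and 0.089 without NC replicate 3. No member passed singly over all genes or adjusted over the list alone. CDC25C was at 9.25 ± 0.263 FPKM in NC and 7.29 ± 0.442 FPKM in mimic libraries, the replication helicase gene MCM5 at 15.1 ± 1.12 and 11.8 ± 0.665 FPKM, and E2F2 at 2.26 ± 0.243 and 1.49 ± 0.223 FPKM (SD, n = 3). In NC replicate 3 the list lay at a median of -0.06 log2 units from NC replicates 1 and 2.

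Genes of the unfolded protein and stress response were higher as a group by a small margin (28 tested, 21 positive, median 0.07, camera adjusted p = 0.045). The adjusted p was 0.84 with an estimated correlation, 0.49 without NC replicate 3, and 0.11 without either mimic replicate 1 or mimic replicate 2. No member passed singly over all genes or adjusted over the list alone. The chaperone genes HSP90B1, DNAJC3 and DNAJB9 were at 281 ± 25.7, 22.6 ± 2.50 and 5.37 ± 0.788 FPKM in NC and at 337 ± 16.3, 27.6 ± 0.245 and 7.19 ± 0.689 FPKM in mimic libraries, while CEBPB was at 15.9 ± 2.24 and 11.7 ± 0.390 FPKM (SD, n = 3). In NC replicate 3 the list lay at a median of -0.14 log2 units from NC replicates 1 and 2.

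**Figure D3:**
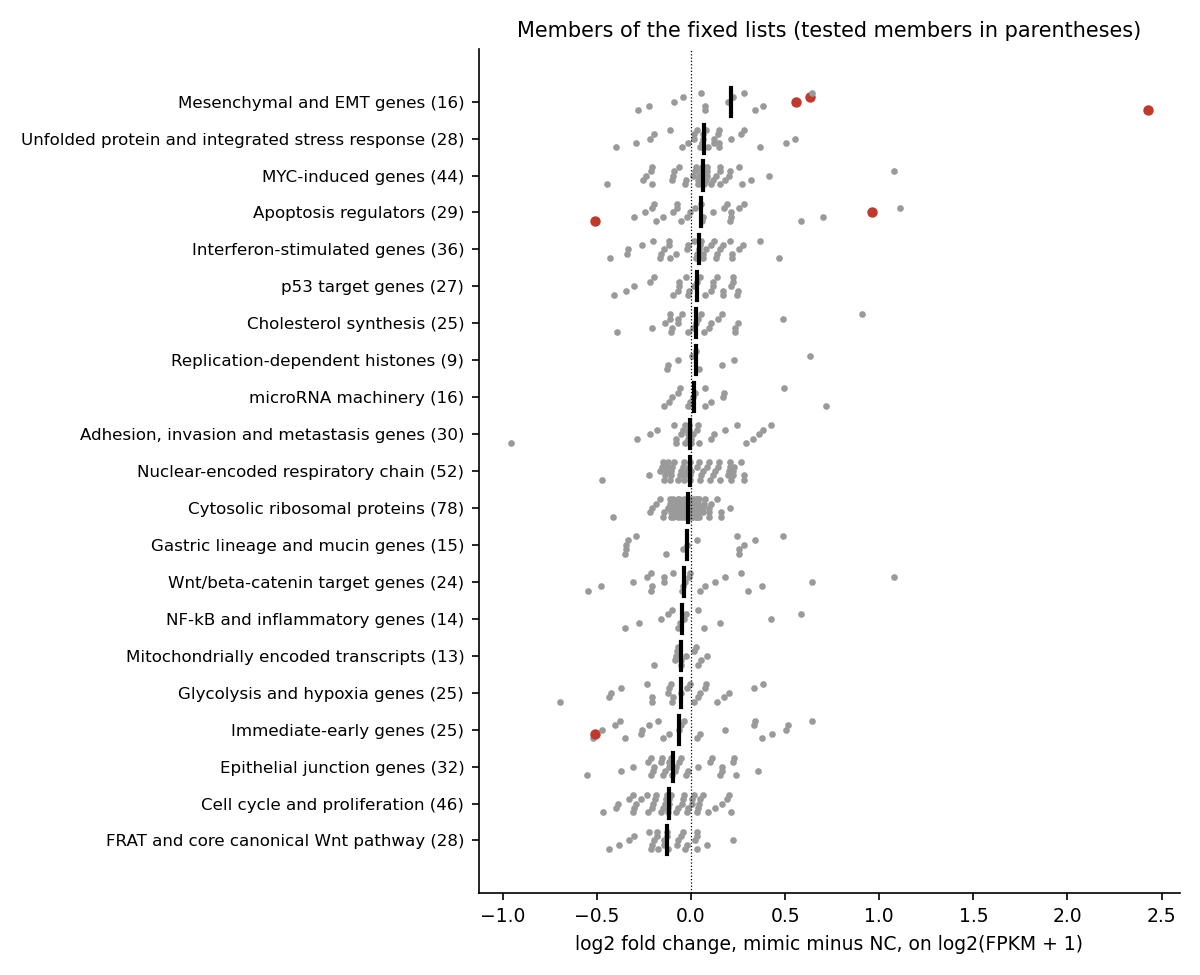
Log2 fold change (mimic minus NC) of each tested member of the lists with at least 9 tested genes, with called genes in red and the list median as a black bar. The mesenchymal list has the highest median (0.21) and the Wnt pathway core the lowest (-0.13).

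Single genes changed in lists that did not move as a group. Among 29 apoptosis regulators (median 0.05, camera adjusted p = 0.57), the anti-apoptotic gene MCL1 fell from 72.9 ± 1.60 to 50.9 ± 0.395 FPKM. The cytochrome c gene CYCS was at 26.2 ± 5.49 FPKM in NC and 42.5 ± 1.08 FPKM in mimic libraries (SD, n = 3). MCL1 was also the called gene among 25 immediate-early genes (median -0.06, adjusted p = 0.48), where 2 genes were higher and 5 lower adjusted over the list alone, with DUSP6 at 5.01 ± 0.186 and 3.63 ± 0.201 FPKM and JUND at 35.5 ± 4.82 and 24.3 ± 1.56 FPKM. Of 15 gastric lineage genes (adjusted p = 0.67), 3 were higher and 3 lower adjusted over the list alone, among them villin, VIL1, at 32.7 ± 2.03 and 46.2 ± 1.5 FPKM, and KLF5 at 81.8 ± 3.85 and 64.3 ± 2.72 FPKM. Of 25 glycolysis and hypoxia genes (adjusted p = 0.57), 1 was higher and 2 lower adjusted over the list alone, including NDRG1, at 2.98 ± 0.444 and 1.45 ± 0.00778 FPKM.

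In the remaining lists with at least 9 tested genes, no gene passed over all genes or adjusted over the list alone. Their camera adjusted p values were 0.64 for p53 targets, 0.67 for interferon-stimulated genes, 0.67 for NF-kB genes, 0.57 for cholesterol synthesis, 0.78 for ribosomal proteins, 0.64 for the nuclear respiratory chain, 0.64 for mitochondrially encoded transcripts, 0.64 for histones and 0.64 for the microRNA machinery. IFI6 was at 143 ± 16.0 FPKM in NC and 106 ± 6.38 FPKM in mimic libraries, SC5D at 4.59 ± 0.610 and 6.82 ± 0.570 FPKM, RPL41 at 453 ± 45.6 and 338 ± 8.90 FPKM, and AGO2, which encodes the Argonaute slicer, at 8.68 ± 0.578 and 9.42 ± 0.209 FPKM (SD, n = 3). Markers of other cell types were low, with 2 fibroblast, 2 leukocyte and 1 endothelial markers above the filter and camera adjusted p of 0.84, 0.25 and 0.84. COL1A1 was at 1.3 ± 0.209 and 0.962 ± 0.0311 FPKM, PDGFRA at 2.81 ± 0.219 and 3.17 ± 0.207 FPKM, LYZ at 5.25 ± 0.244 and 3.95 ± 0.235 FPKM, CD68 at 1.66 ± 0.593 and 1.35 ± 0.135 FPKM, and ESAM at 2.46 ± 0.505 and 2.33 ± 0.488 FPKM. LYZ was lower when adjusted over its list alone, and it also belongs to the gastric list.

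Genes with a site for the miR-3648 seed in the 3' UTR were lower in mimic libraries than genes without one. The 212 tested genes with a 7mer-m8 or 7mer-A1 site had a median log2 fold change of -0.14, against -0.0011 in 9948 genes without one, and 80.2% of them had a negative value, against 50.4%. The site is rich in GC, and the transcripts that carry it had a mean GC content of 57.4%, against 49.2% in the others. Among the 56 words of equal CpG content the 7mer-m8 site ranked 7 from the lowest, and the median difference over the 56 words was -0.12, near the -0.14 of the site itself. The camera p for the 212 genes was 8.5e-10 at the preset correlation and 0.20 with an estimated correlation. H2AFX and SERINC5 were the called genes with a site among the 18 that fell, and no called gene that rose had one. FRAT2 had 1 7mer-m8 site in its 3' UTR of 1374 nucleotides, FRAT1 and MYC had none in 3' UTRs of 1622 and 476 nucleotides, and each of the 3 genes had 1 in its coding sequence.

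Agreement between libraries followed GC content as well as group. Pearson's r of log2(FPKM + 1) across tested genes was 0.982 between NC replicates 1 and 2 and averaged 0.984 among mimic libraries. NC replicate 3 averaged 0.967 with the other NC libraries and 0.979 with the mimic libraries. Its deviation from NC replicates 1 and 2 ran against transcript GC content across genes (Spearman's rho -0.71), as did the fold change between groups (rho -0.50), and genes are not independent replicates. The first principal component, with 40.7% of the variance, placed NC replicate 3 on the side of the mimic libraries.

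**Figure D4:**
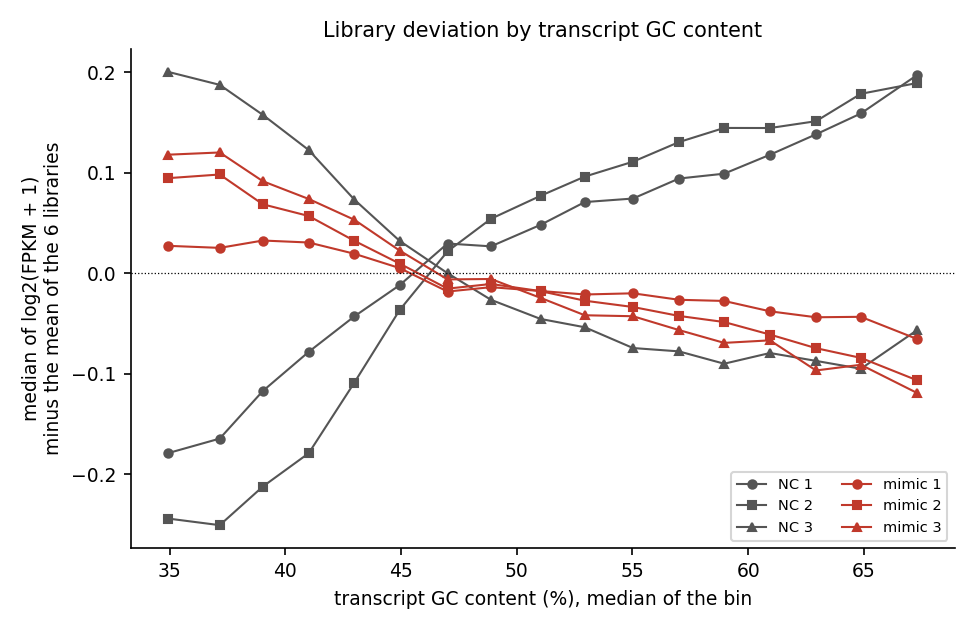
Median deviation of each library from the mean of the 6 libraries, in bins of transcript GC content 2 percentage points wide, open at both ends. NC replicates 1 and 2 run from -0.18 and -0.24 in the lowest bin to 0.20 and 0.19 in the highest, while NC replicate 3 runs from 0.20 to -0.06, in the direction of the mimic libraries, which lie between 0.027 and 0.12 in the lowest bin.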

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

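The GC and length corrections, the fits that combine GC correction with leaving out NC replicate 3, the rank form of camera, and GC correction with an estimated correlation in camera were chosen after the data were seen. The count of 42 genes (24 higher, 18 lower) stayed within 1.5 times under both other pseudocounts, both filters, both scalings and the fit without an intensity trend, which called 31 to 42 genes, 31 to 42 of them shared. With library weights 1355 genes were called (563 higher, 792 lower), with NC replicate 3 given a weight of 0.21. A minimum absolute change of 1 log2 unit left 9 genes (5 higher, 4 lower) by construction. GC correction gave 102 genes (61 higher, 41 lower), GC and length correction 175 (96 higher, 79 lower), and GC correction without NC replicate 3 gave 110 (65 higher, 45 lower), with 39, 39 and 33 of the 42 still called. Leaving out 1 library gave 8 to 1527 genes, 4 to 798 higher and 2 to 729 lower, the highest values without NC replicate 3. Fewer libraries lower the power. The 1527 calls came down to the 110 above with GC correction. All 42 genes, or all that were tested, kept their sign under every alternative.

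A replicate block gave 11 genes (6 higher, 5 lower), all among the 42. Deviations of equally numbered libraries correlated at 0.04, -0.04 and 0.07 across genes. NC replicates 1 and 3 correlated best with the mimic library of their own number, and NC replicate 2 did not. So few libraries cannot settle whether the numbers mark pairs. The block also ended the call of the unfolded protein list (adjusted p = 0.10).

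FRAT2 passed the limma test with library weights (-0.34, adjusted p = 0.027) and without NC replicate 3 (-0.35), and its log2 fold change ran from -0.35 to -0.27 over the libraries left out. FRAT1, without the filter, passed with library weights (-0.50, adjusted p = 0.0064) and without NC replicate 3, with a range of -0.48 to -0.33. With GC correction and NC replicate 3 left out neither passed: FRAT2 went from -0.35 (SE 0.061) to -0.18 (SE 0.062, adjusted p = 0.18) and FRAT1 from -0.48 (SE 0.098) to -0.28 (SE 0.091, adjusted p = 0.17), since the differences shrank at a similar error. FRAT1 has no value with a filter of 5. MYC did not pass in any alternative (adjusted p from 0.40 to 0.74). The cause was not tested for either gene.

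Of the 24 lists, 4 passed with camera at the preset correlation, 0 with an estimated correlation, with or without GC correction, 2 with fry in 1 direction and 9 with fry in either direction, and 1 to 8 with a library left out, the lowest without NC replicate 3 and the highest without NC replicate 2. At the preset correlation 5 lists passed after GC correction and 6 after GC and length correction, the 4 of the main comparison among them. After GC correction their camera adjusted p values were 9.9e-07 for mesenchymal, 0.0020 for unfolded protein, 0.0032 for cell cycle and 0.0049 for Wnt core genes. The unfolded protein list also failed with upper-quartile scaling (adjusted p = 0.056) and with rank-based camera (0.065). The direction of the Wnt target list, which did not pass, turned with GC correction (adjusted p = 0.92, and 0.98 with an estimated correlation) and with GC and length correction (0.90). The cause was not tested.

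For seed sites the difference in median was -0.10 for sites in coding sequence, -0.059 in a linear model with UTR length and GC content, -0.0536 after GC correction and -0.0452 after GC and length correction, against -0.14 in the main comparison, so part of it goes with GC content. Among markers of other cell types, CD68 ranged from -0.29 to 0.02 (0.0186 without NC replicate 2) and ESAM from -0.16 to 0.048 over the libraries left out, and ESAM was at 0.0296 after GC correction, 0.0064 after GC and length correction and 0.10 after GC correction without NC replicate 3. Without depth, the precision of low values such as those of FRAT1 cannot be given. The count models planned for raw counts were not run, since the values are FPKM.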

Other observations

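GC correction, chosen after the data were seen, brought 63 further genes past the limma threshold, and the genes named here were picked after their values were seen. Among them were genes of the actin cytoskeleton that lay higher in mimic libraries before and after correction. The LIM protein gene FHL2 had a log2 fold change of 0.53 before (adjusted p = 0.084) and 0.54 after correction (adjusted p = 0.027), the focal adhesion gene ZYX 0.38 and 0.53 (adjusted p = 0.25 and 0.033), the filamin gene FLNA 0.30 and 0.43 (adjusted p = 0.30 and 0.034), and the calponin gene CNN2 0.38 and 0.48 (adjusted p = 0.16 and 0.033). The matricellular gene CYR61 moved from 0.64 to 0.68 (adjusted p = 0.073 and 0.020) and ANKRD1 from 0.49 to 0.43 (adjusted p = 0.073 and 0.026). Both are known targets of YAP.

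All tests in the rest of this part were chosen after the results they bear on had been seen. The real split of the 6 libraries called 42 genes and the highest of the other 9 splits called 7, so 1 of the 10 splits, the real one, gave as many. With 10 splits a share under 0.05 cannot be reached.

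NC replicate 3 correlated better with the mimic libraries than with NC replicates 1 and 2, with a difference in mean r of -0.011. A mislabelled mimic library is argued against: over the 110 genes called after GC correction without NC replicate 3, that library lay at a median position of 0.21 (quartiles 0.0077 and 0.52), where 0 is the mean of NC replicates 1 and 2 and 1 the mimic mean. Without correction the median position over the 1527 genes called without that library was 0.83 (quartiles 0.53 and 1.14), near the mimic level, as either a wrong label or a shared GC trend would give. The overlapping genes TXNDC5 and BLOC1S5-TXNDC5 also place NC replicate 3 with the mimic libraries (10.1 and 154 FPKM, against 13.9 to 15.2 and 176 to 184 in mimic libraries), a single locus where NC replicates 1 and 2 stand apart from the other 4 libraries. A difference between libraries that depends on GC content may account for the better correlation with mimic libraries. After GC correction the difference in mean r was 0.00023, so NC replicate 3 was then about as near to one group as to the other. Its mean r was 0.9815 with NC replicates 1 and 2, which correlated at 0.9842 with each other, and 0.9813 with mimic libraries. The first principal component after correction placed it at -4.3, between NC replicates 1 and 2 (-12.6 and -12.0) and the mimic libraries (8.8 to 10.5). The correction thus did not return it fully to the NC group. Whether NC replicates 1 and 2 were prepared apart from the other 4 libraries is not recorded and stays open, and a GC trend shared by NC replicate 3 and the mimic libraries cannot come from the mimic alone. No biological explanation was tested.

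MYC was high in mimic replicate 1 alone, 2.74 log2 units above the next library. The 43 tested MYC-induced genes without MYC were not shifted with it. They differed by a median of -0.00089 from mimic replicates 2 and 3, at percentile 32.8 of 10000 lists matched on expression, and went both ways. Higher MYC activity in that library was thus not seen in these genes, but a comparison that rests on 1 library leaves it open. Jumps of single genes in single libraries stay open as well. Each of the other 5 libraries had at least 7 genes more than 1 log2 unit outside the range of all others, and mimic replicate 1 had 16, but upward jumps like that of MYC numbered 7 in mimic replicate 1 and 1 to 8 in the others. The largest upward jump of the other libraries was 3.05 log2 units in NC replicate 3 and 1.2 to 2.0 in the remaining 4. TUBB3 was another upward jump in mimic replicate 1, at 29.1 FPKM there and 6.35 to 8.68 FPKM elsewhere. In the same library SENP3-EIF4A1, a read-through gene by its name, was at 48.2 FPKM, against 0 to 19.9 elsewhere. SENP3 was at 4.57 FPKM there and 12.8 to 20.2 FPKM elsewhere, so these 2 jumps went in opposite directions. Whether reads were divided differently between those gene models was not tested. What makes such jumps cannot be read from FPKM.

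AARSD1 fell while PTGES3L-AARSD1 rose. Their summed FPKM differed by 0.23 log2 units (SE 0.11), so a different division of reads between overlapping gene models may account for both calls. The overlapping pair of TXNDC5 and BLOC1S5-TXNDC5 showed that such divisions also differ within a group: TXNDC5 was at 131 and 135 FPKM in NC replicates 1 and 2 and at 10.1 FPKM in NC replicate 3, where BLOC1S5-TXNDC5 was at 154 FPKM against 1.15 and 1.48, so the split there does not follow the groups. A change in which transcript the cells make at the AARSD1 locus was not tested and stays open.

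A hypothesis on the seed sites was that genes with a miR-3648 site were lower beyond what GC-rich words give. After GC and length correction the 7mer-m8 site ranked 1 of 56 words, with a difference in median of -0.0461 against a median of -0.02 over the words, from a rank of 7 without correction and 4 with GC correction alone. The next word lay at -0.0449 and 7 other words within 1 SE (0.014) of the site, so the site does not stand apart from words like it. The camera p for site-bearing genes was then 0.0024 at the preset and 0.0083 at the estimated correlation, against genes without a site and not against matched words. An effect of the site beyond that of similar words stays open.

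Lists written after the called genes were seen asked whether the changes were wider than the 42 called genes of the main comparison, which were left out. For actin genes driven by SRF and MRTF (31 tested, 20 positive) the median log2 fold change was 0.08 (0.0758), with a camera p of 0.012 at the preset (0.035 adjusted over the 3 lists) and 0.41 at an estimated correlation. For YAP and TEAD targets (15 tested, 9 positive) it was 0.07 (0.0665), with camera giving 0.064 and 0.16 in the same tests. For autophagy and lysosome genes (36 tested, 15 positive) it was -0.03 (-0.0327), with 0.34 and 0.54 in the same tests. After GC correction the medians were 0.097, 0.065 and -0.051, with a camera p of 0.00014, 0.064 and 0.44 at the preset and 0.16, 0.12 and 0.49 at an estimated correlation, so the actin list passed at the preset alone both times. The tests after GC correction kept 4, 2 and 2 members of the lists that were called only after that correction, among them FHL2, ZYX, FLNA and CNN2. They therefore cannot show a change wider than the genes called there. A wider rise of actin or YAP target genes, or a wider fall of autophagy genes, may or may not hold, and members went both ways in each list.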
